A study of Rattus norvegicus with 14 samples.

How the data were processed

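RNA from rat IEC-6 cells was measured on 14 one-colour Affymetrix arrays, 1 RNA channel per array. Per the labels, cells were kept for 72 h with DMSO as the solvent control, 100 µM indomethacin, 100 µM NS-398 or 1 µM SC-560, and RNA was labelled after 2 rounds of amplification by in vitro transcription. The 4 groups held 4 DMSO, 2 indomethacin, 4 NS-398 and 4 SC-560 arrays. Array labels carried a digit, 1 or 2, with or without the suffix b. The 6 arrays without the suffix and the 8 with it are called the 2 label sets here. Both indomethacin arrays carried the suffix. The meaning of the suffix was not given in the sources used here.

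The submitters' design text states that cultures were pooled and that several chips were hybridised per biological sample. The p-values therefore measure the spread between arrays, which may be technical, and not the spread between independent experiments.

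The values were deposited by the authors as linear signal intensities for 31099 probe sets per array, and per the labels all probe sets were scaled to a target signal of 500. The scaling was checked on the deposited intensities: the mean of each array after trimming its extremes lay between 500.163 and 500.173. The software that summarised the probes was not given in the sources used here. No other normalization between arrays was found, and none was added in the main analysis. The number of arrays limits the precision, and no counts or depths apply.

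Probe sets were named from the platform annotation, with symbols updated through gene identifiers in a RefSeq table of the assembly GRCr8, which was used for names only. Of the probe sets, 20832 had 1 symbol, 436 had several and were not named, and 9831 were not listed in the annotation and stay unnamed here. For 20764 probe sets the gene identifier was found in the RefSeq table, and 68 kept the annotation's symbol. No genome was used and no coordinates are given. The 57 control probe sets were left out of the tests. A probe set was tested if its signal reached 100 on at least 2 arrays, which left 17515 probe sets and 9840 named genes. A gene was represented by its probe set with the highest mean log2 signal.

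Signals were transformed as log2(signal + 50) and fitted with limma 3.58.1 under R 4.3.3. The model had 1 mean for each of the 4 groups and a term for the label set, and was fitted to all arrays with empirical Bayes moderation and an intensity trend. Adjusted p-values are Benjamini-Hochberg values from limma over all probe sets tested, and a probe set was called at an adjusted p under 0.05. Errors after ± on log2 changes are standard errors from this fit, and errors on signals are standard deviations. Comparisons were each drug against DMSO, the mean of indomethacin and NS-398 against the mean of SC-560 and DMSO, and each pair of drugs. Whether the effect of NS-398 or SC-560 differed between the label sets was tested as an interaction in a fit without the indomethacin arrays.

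Before the data were examined, 28 gene lists were fixed, holding 734 genes, of which 541 were measured. They covered the calpain system, prostaglandin synthesis, stress responses, cell cycle, metabolism, cytoskeleton and matrix, signalling pathways and markers of cell types. The calpain genes are a list that the study's own publications drew from these arrays, so their direction is not independent evidence. Lists were tested with camera at a preset correlation of 0.01 between genes, using 1 probe set per gene, and again with an estimated correlation and with fry. Benjamini-Hochberg adjustment ran over the 28 lists of a comparison.

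The genes named were also fixed by rule before the data were examined. For each drug against DMSO and for the combined contrast these were the 10 largest rises and 10 largest falls among called genes with a mean signal of at least 200 in the higher group and the same sign in each label set that held all groups compared. From each list, up to 2 called members in each direction with the smallest adjusted p were added. Ptn, Ptgs1, Ptgs2 and the calpain genes measured were always included. The 5 largest differences in each direction were taken for pairs of drugs. Predicted loci were passed over.

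The labels shared across groups were checked as a possible pairing. Arrays with the same label deviated together from their group means (r from 0.69 to 0.79), but arrays of the same set with the other digit did so as much (0.70 to 0.81). After the means of group and set were removed, arrays with the same label correlated between -0.08 and 0.06. The shared labels thus carried the label set, which is in the model, and no further pairing.

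The fit was tested on simulated data with the spread of the real arrays and 200 changed probe sets among 17515. At a simulated log2 change of 0.5, 51% were recovered for indomethacin against DMSO, 64.5% for NS-398, 63.5% for SC-560 and 79.5% for the combined contrast. At a log2 change of 1 the shares were 90%, 95.5%, 94.5% and 98.5%, in the same order. The false share of the calls, in that order, was 4.67%, 3.73%, 5.22% and 7.56% at 0.5. At 1 it was 6.74%, 4.98%, 5.03% and 6.64%. All of these come from 1 simulated draw of the spread, so small departures from 5% are not resolved.

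Alternatives fixed before the data were examined were other pseudocounts, filters and scalings, no label set term, the replicate labels as a block, a random block, each label set alone, the compared groups alone, no intensity trend, a fold minimum and leaving out each array in turn. Chosen after seeing the data were a random block for arrays of 1 group and label set, correlations between drugs from different label sets, and pseudocounts of 16 and 200 for the drug effect by label set. Splits of the arrays that keep the label sets balanced, and draws of the groups within each set, were also counted after seeing the data.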

Results

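IEC-6 is a line of non-transformed epithelial cells from rat small intestine. Monolayers were exposed for 72 h to DMSO alone or to 1 of 3 non-steroidal anti-inflammatory drugs. Indomethacin, which blocks both cyclooxygenases, and NS-398, which prefers cyclooxygenase-2, were used at 100 µM. SC-560, which prefers cyclooxygenase-1, was used at 1 µM, so the doses of the drugs differ. There were 4 arrays each for DMSO, NS-398 and SC-560, and 2 for indomethacin. The submitters describe indomethacin and NS-398 as slowing the migration of these cells and SC-560 as lacking this effect, and the comparisons follow that division. The median signal of the 14 arrays lay between 97.8 and 118, and between 49.7% and 52.4% of probe sets reached a signal of 100.

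The label sets differed more than any treatment. The first principal component held 69.2% of the variance and separated the 6 arrays without the suffix b from the 8 with it, and 10328 of 17515 probe sets (59.0%) differed between the sets in the limma fit. NS-398 arrays of both sets separated from the DMSO and SC-560 arrays on the second component (7.53% of the variance), with the indomethacin arrays in between. The ratio of 3' to 5' signal of the beta-actin control, a measure of RNA quality and labelling, was 1.498 to 1.639 without the suffix and 1.22 to 1.34 with it. The same ratio of the Gapdh control overlapped, at 0.902 to 0.990 without the suffix and 0.955 to 1.002 with it. Both indomethacin arrays carried the suffix, so that its comparisons with the other groups also rest on the difference between the sets fitted from the other groups. This assumes the same difference between the sets in every group. The effect of NS-398 by label set, given below, departs from that for part of the genes.

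**Figure D1:**
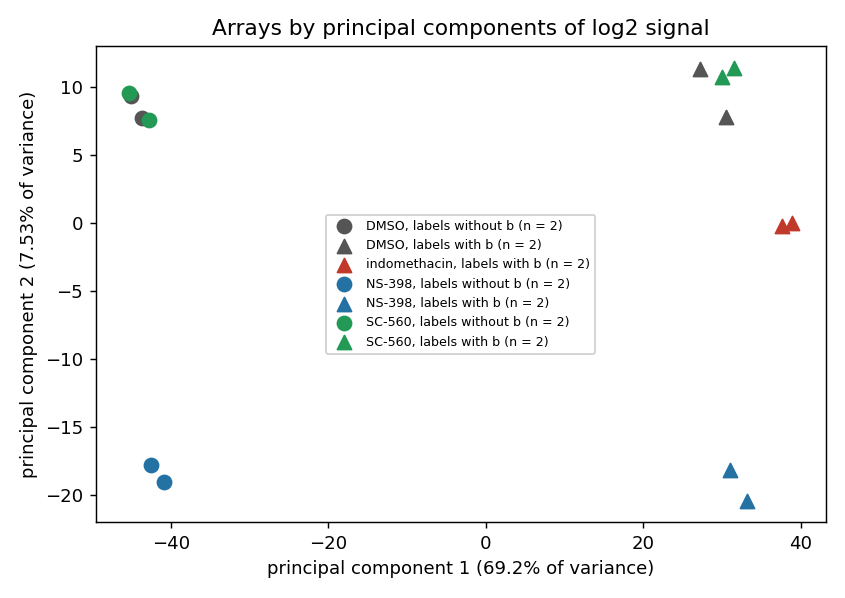
Each point is 1 array, placed by its scores on principal components 1 and 2 of the log2 signals (arbitrary units), coloured by group, with circles for labels without the suffix b and triangles for labels with it. The 2 label sets lie apart on component 1 (69.2% of the variance), and the 4 NS-398 arrays lie lowest on component 2.

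Indomethacin against DMSO addresses what the first of the drugs that slow migration does to these cells. Fabp4, a carrier of fatty acids, rose 4.86-fold after the addition of 50 to each signal (log2 change 2.28 ± 0.16, limma adjusted p 5.45e-07). Its signal was 1040 ± 13.1 on the 2 indomethacin arrays and 159 ± 23.5 on the 2 DMSO arrays of the same label set. Agr2, a protein disulfide isomerase of secretory epithelia, rose by a log2 change of 1.45 ± 0.19, Clu, a secreted chaperone, by 1.37 ± 0.09, Raph1, a regulator of actin at the leading edge, by 1.21 ± 0.13, and Aldh3a1, an aldehyde dehydrogenase, by 1.09 ± 0.16. Among the falls were the noncoding RNA H19 (-1.33 ± 0.12), Dock11, which activates the small GTPase Cdc42 (-1.22 ± 0.10), the matrix genes Mfap4 (-1.20 ± 0.16) and Nid1 (-1.12 ± 0.10), and Tagln, an actin-binding protein of smooth muscle (-1.65 ± 0.27). Agr2, with a mean DMSO signal of 83.4 in the same label set, had 1.70 at a pseudocount of 16 and 0.89 at 200. Limma adjusted p-values of these genes ran from 2.54e-07 for Clu to 0.00262 for Tagln.

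Genes of the unfolded protein response, which senses misfolded protein in the endoplasmic reticulum, rose under indomethacin. Of 21 measured, 11 rose and none fell (13 rose when adjusted over the list alone), among them Sdf2l1 (0.68 ± 0.08) and the chaperone Hsp90b1 (0.45 ± 0.06). The list passed camera at an adjusted p of 8.05e-14 and at an adjusted p of 0.0225 with an estimated correlation. Of 29 genes of ATF4 and the integrated stress response, 8 rose and none fell (12 adjusted over the list alone), with the amino acid transporter subunit Slc3a2 at 0.70 ± 0.06. Camera gave this list an adjusted p of 3.45e-09, against an adjusted p of 0.15 with an estimated correlation. Of 20 targets of NRF2, the regulator of antioxidant genes, 5 rose and none fell (10 adjusted over the list alone), including the quinone reductase Nqo1 (0.65 ± 0.07) and the aldo-keto reductase Akr1b8 (0.63 ± 0.07). The adjusted p of the NRF2 list was 6.03e-07, and 0.0448 with an estimated correlation. Of 20 genes of cholesterol synthesis 3 rose (5 over the list alone; camera adjusted p 9.13e-05, adjusted p 0.15 with an estimated correlation).

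Matrix and inflammatory genes moved the other way under indomethacin. Of 34 extracellular matrix genes 6 fell and none rose (10 fell and 1 rose when adjusted over the list alone), with Eln, the elastin gene, at -0.71 ± 0.09 beside Nid1. Of 19 genes of NF-kB and inflammation 4 fell (6 adjusted over the list alone), including the chemokines Ccl2 (-0.97 ± 0.14) and Cxcl1 (-0.84 ± 0.12). The matrix list had a camera adjusted p of 2.75e-05 and the inflammatory list one of 2.05e-04; both had an adjusted p of 0.15 with an estimated correlation. Arg1, which makes ornithine, fell by 0.77 on the log2 scale as the called member of the polyamine list of 12 (2 fell over the list alone; camera adjusted p 0.00575, adjusted p 0.15 with an estimated correlation). Of 12 markers of fibroblasts and smooth muscle 3 fell (3 over the list alone), Tagln and Cald1 (-0.48 ± 0.07) among them, but 6 of 12 lay above 0 and the list did not pass (camera adjusted p 0.108). Of 12 epithelial markers 1 rose (2 over the list alone; adjusted p 0.0166, adjusted p 0.15 with an estimated correlation), and of 26 genes of glycolysis and hypoxia 1 rose (2 over the list alone; adjusted p 0.00416, adjusted p 0.547 with an estimated correlation). The single calls in these 2 lists did not hold: Krt8 lost its call when any 1 of the 6 arrays was left out (adjusted p 0.0606 to 0.235), and Vegfa without DMSO array 1b or 2b or either indomethacin array (0.07 to 0.351). Without DMSO array 1b both lists had an adjusted p of 0.0695, and without indomethacin array 2b the glycolysis list had one of 0.0784. In all, 9 of the 28 lists passed camera, 2 of them with an estimated correlation.

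In total 572 of 17515 probe sets were called for indomethacin in limma, 264 higher and 308 lower, of which 211 differed by at least 1.5-fold. With a random block for arrays of 1 group and label set, chosen after seeing the data, 283 were called. Of 45 named genes that were called, 25 stayed so when any 1 array was left out. F13a1, a transglutaminase subunit, fell (log2 change -2.51 ± 0.50, limma adjusted p 0.0104) to signals of 55.01 and 94.33 on the indomethacin arrays, so that the size depends on the pseudocount (-2.84 at 16 and -1.71 at 200). It was not among the 25: its adjusted p was 0.0542 without DMSO array 1b, 0.123 without indomethacin array 1b and 0.0696 without indomethacin array 2b. The count fell to 158 and 100 without indomethacin array 1b or 2b, to 239 and 379 without DMSO array 1b or 2b, and to 2 without the label set term, while set b alone gave 1174.

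**Figure D2:**
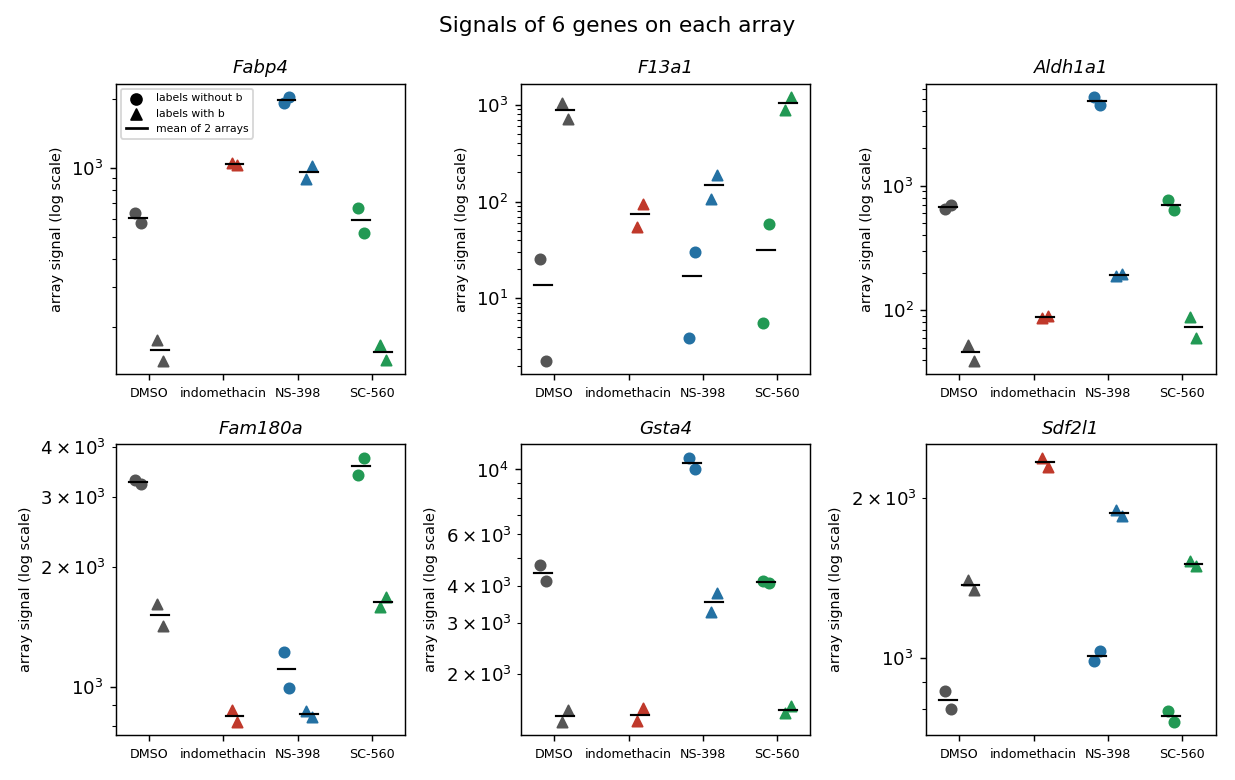
Array signal (log scale) of 6 genes on each of the 14 arrays by group, with circles for labels without the suffix b, triangles for labels with it and a bar at the mean of each pair. Fabp4 was higher on the indomethacin and NS-398 arrays than on the DMSO arrays of the same label set, and the level of several genes also differed between the sets.

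NS-398 against DMSO had the larger number of calls. Aldh1a1, a retinaldehyde dehydrogenase, rose 4.11-fold on the same scale (log2 change 2.04 ± 0.24, limma adjusted p 3.95e-05), with a log2 change of 2.74 in the set without the suffix and 1.34 in set b. Its mean signal on the DMSO arrays of set b was 46.0, so that the added 50 lowers the latter value. Fabp4 rose by a log2 change of 1.96 ± 0.12 (1.64 and 2.27 in the 2 sets), Hsd11b1, which regenerates active glucocorticoid, by 1.496 ± 0.129 (1.096 and 1.896), Scara5, a ferritin receptor, by 1.33 ± 0.08 (1.24 and 1.42) and the glutathione transferase Gsta4 by 1.25 ± 0.07 (1.23 and 1.26). The trefoil peptides of mucous epithelia, Tff1 (1.41 ± 0.29) and Tff2 (1.78 ± 0.33), also rose, from mean DMSO signals of 42.2 and 10.4. At such signals the size depends on the pseudocount: it was 1.86 and 2.65 at 16, and 0.76 and 0.84 at 200. Among the falls were Fam180a (-1.16 ± 0.13), Dock11 (-1.10 ± 0.08), the histone gene Hist2h2be (-1.04 ± 0.11), Ppl, a desmosomal linker (-0.95 ± 0.12), and Afap1l2 (-0.88 ± 0.07). The largest limma adjusted p among these genes was 0.00436, for Tff1.

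Targets of NRF2 formed the clearest group under NS-398. Of 20 measured, 15 rose and none fell (17 adjusted over the list alone), and their median log2 change was 0.52 in the set without the suffix and 0.41 in set b. The interaction of the list with the set had a camera adjusted p of 0.241, but the effect on 3 of the 20 differed between the sets. Gclm was 1 of these, with a mean signal 3.14 times that of DMSO without the suffix and 1.08 times in set b. Besides Gsta4, Akr1b8 rose by 0.92 ± 0.05. The list passed camera at an adjusted p of 8.59e-19 and at an adjusted p of 0.00222 with an estimated correlation. Of 26 genes of glycolysis and hypoxia 16 rose and none fell (19 adjusted over the list alone), including Vegfa, the vascular growth factor (1.02 ± 0.07), and the glycolytic enzyme Tpi1 (0.57 ± 0.05). This list had a camera adjusted p of 1.6e-10, but an adjusted p of 0.257 with an estimated correlation, and its median was 0.12 without the suffix and 0.51 in set b. For 10 of the 26 genes the effect differed between the sets in the limma interaction. The interaction of the list had a camera adjusted p of 1.47e-08, and an adjusted p of 0.0993 with an estimated correlation. Of 19 genes of NF-kB and inflammation 8 rose and none fell (9 adjusted over the list alone), among them the inhibitor Nfkbia (0.70 ± 0.08) and the chemokine Cxcl12 (0.50 ± 0.07), with medians of 0.28 and 0.32 in the sets. Its camera adjusted p was 4.87e-04, and its adjusted p with an estimated correlation was 0.252.

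Of 29 genes of ATF4 and the integrated stress response 10 rose under NS-398, such as Ddit4, an inhibitor of mTORC1 (0.87 ± 0.06), and 2 fell, Pck2 (-0.38 ± 0.08) and Atf5, whose adjusted p was 0.0501 without DMSO array 1b (12 rose and 3 fell over the list alone). The camera adjusted p was 0.0073, and 0.441 as adjusted p with an estimated correlation. The unfolded protein response list did not pass (adjusted p 0.651), with the same counts over the list alone: 1 member rose, Sdf2l1 (0.35 ± 0.06), and 2 fell, including Dnajc3 (-0.29 ± 0.07). Of 16 Wnt targets 6 rose, with the cyclin Ccnd1 at 0.76 ± 0.07 and the hyaluronan receptor Cd44 at 0.65 ± 0.09, and of 16 p53 targets 5 rose, with Gadd45a at 0.51 ± 0.09. Over the lists alone 7 rose in each, and 2 Wnt targets fell. Both lists had a camera adjusted p of 0.00852, and adjusted p-values of 0.257 and 0.289 with an estimated correlation. Of 33 genes of the actin cytoskeleton 7 fell and none rose, including the tropomyosin Tpm1 (-0.40 ± 0.05; 8 fell and 1 rose over the list alone; adjusted p 0.00852, adjusted p 0.34 with an estimated correlation). Of 30 mitotic genes 3 fell, Mki67 among them (-0.23 ± 0.05), and 1 rose, Cks2 (0.26 ± 0.05; 4 fell and 1 rose over the list alone). The mitotic list had an adjusted p of 0.0321, an adjusted p of 0.703 with an estimated correlation, and 0.105, 0.177, 0.236 and 0.196 without DMSO arrays 1b and 2b and NS-398 arrays 1b and 2b in turn. Some of these lists had medians further from 0 in the set without the suffix. The medians there and in set b were 0.27 and 0.03 for ATF4, 0.34 and 0.07 for Wnt and -0.16 and -0.01 for actin, against 0.14 and 0.20 for p53. The mitotic list lay lower in set b only, with medians of 0.06 and -0.25. The interaction with the set had a camera adjusted p of 0.00043 for ATF4, 0.0647 for Wnt and 0.0192 for actin, and with an estimated correlation an adjusted p of 0.232, 0.232 and 0.109. Single members stood out in lists that did not pass: Sat1, which breaks down polyamines, rose by 1.10 ± 0.09 and the protease Adamts1 by 1.06 ± 0.08. Matrix genes went both ways, with 9 of 34 falling, such as Nid1 (-0.73 ± 0.08), and 3 rising, such as Dcn (0.80 ± 0.10), which is also on the list of fibroblast markers; of those 12 markers 2 rose and 3 fell (5 and 3 over the list alone). Over the matrix list alone 6 rose and 10 fell, and its camera adjusted p was 0.0992. The effect on 11 of the 34 matrix genes differed between the sets, with list medians of -0.18 without the suffix and 0.03 in set b. The interaction of the matrix list had a camera adjusted p of 0.0372, and an adjusted p of 0.373 with an estimated correlation.

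Some calls needed both label sets: Tff2, Gadd45a, Sdf2l1, Mki67 and Atf5 were not called in the set without the suffix alone, Tff1 and Cks2 not in set b alone, and Dnajc3 in neither. In limma 2366 of 17515 probe sets were called for NS-398, 1247 higher and 1119 lower, of which 322 differed by at least 1.5-fold. Of 90 named genes that were called, 71 stayed so when any 1 array was left out. Within the label sets alone the counts were 1660 without the suffix and 2493 in set b. Without the label set term 111 were called. Of the 2366 calls 2364 had the same sign in both sets, but calling on the effect averaged over the sets favours such agreement. Over all probe sets the changes in the 2 sets correlated with r = 0.274. Of 523 probe sets called in each set alone, 434 had the same direction and 89 opposite directions.

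SC-560 against DMSO gave no call at its lower dose. Limma called 0 of 17515 probe sets, and the smallest adjusted p was 0.216. At an unadjusted p under 0.05 there were 1263 probe sets, where 876 would be expected by chance. No member of the NRF2, unfolded protein response or NF-kB lists was called, and their median log2 changes were -0.02, -0.02 and 0.02; over the list alone 1 NRF2 target rose. Mitotic genes lay lower as a list (median log2 change -0.11, with 3 of 30 above 0) and epithelial markers higher (median 0.15 over 12), with camera adjusted p-values of 1.21e-06 and 0.0121 and adjusted p-values of 0.732 and 0.552 with an estimated correlation. The 12 markers of fibroblasts and smooth muscle had a camera adjusted p of 0.0361 and an adjusted p of 0.568 with an estimated correlation. The epithelial list had an adjusted p of 0.134 without DMSO array 1b, and the fibroblast list one of 0.133, 0.322, 0.0693 and 0.231 without DMSO arrays 2 and 2b and SC-560 arrays 1b and 2b in turn. The count of probe sets was 3 in set b alone, 2 in the set without the suffix alone and 2 without the intensity trend.

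The drugs that slow migration were compared together with SC-560 and DMSO. Among the named genes Fabp4 had the largest rise (log2 change 2.13 ± 0.10, limma adjusted p 1.94e-09), and Clu rose by 1.03 ± 0.06. Aldh1a1 (1.27 ± 0.20) and Tff2 (1.37 ± 0.27) rose from signals under 100 on some or all DMSO arrays, and Tff2 had 2.04 at a pseudocount of 16 and 0.62 at 200. In set b Aldh1a1 had signals of 87.45 and 89.54 on the indomethacin arrays and 188.5 and 195.4 on the NS-398 arrays. The DMSO and SC-560 arrays of that set had 39.24 to 88.09, so its rise came mostly from NS-398. F13a1 (-1.94 ± 0.32), Tagln (-1.25 ± 0.17), Dock11 (-1.12 ± 0.06), Fam180a (-1.10 ± 0.10) and Mfap4 (-1.07 ± 0.10) fell, with limma adjusted p-values of at most 0.000826. F13a1 had signals of 2.238 to 58.03 on the 6 arrays without the suffix, so its fall rests on set b, and it had -2.21 at a pseudocount of 16 and -1.34 at 200. Of 34 extracellular matrix genes 13 fell, Nid1 (-0.87 ± 0.07) and Eln (-0.50 ± 0.06) among them, and 1 rose, Vcan, whose call was lost without indomethacin array 1b (adjusted p 0.0527). The matrix list (15 fell and 3 rose over the list alone) had a camera adjusted p of 4.89e-05 and an adjusted p of 0.172 with an estimated correlation. For 11 of these 34 genes the effect of NS-398 differed between the label sets. Of 29 focal adhesion genes 6 fell, such as the kinase Pak1 (-0.37 ± 0.06) and the integrin adaptor Parva (-0.28 ± 0.04), and 1 rose, the integrin Itgb4 (0.46 ± 0.08; 9 fell and 3 rose over the list alone). The focal adhesion list had an adjusted p of 0.0409, an adjusted p of 0.172 with an estimated correlation, and 0.0842, 0.0673 and 0.0737 without indomethacin array 1b, NS-398 array 1 and SC-560 array 2b in turn. Of 33 genes of the actin cytoskeleton 3 fell, including Tpm1 (-0.39 ± 0.04) and Ezr (-0.26 ± 0.04; 3 fell over the list alone), and the list did not pass (adjusted p 0.201). Of the 12 markers of fibroblasts and smooth muscle 3 fell (4 fell and 2 rose over the list alone), and that list did not pass either (adjusted p 0.205).

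NRF2 targets were higher under the mean of the drugs that slow migration. For the unfolded protein response the mean combines unlike effects, as that list did not pass under NS-398. The glycolysis and ATF4 lists passed camera under each drug, though under indomethacin only 1 of 26 genes of glycolysis and hypoxia rose. Of 20 NRF2 targets 16 rose (17 over the list alone; adjusted p 1.77e-18, adjusted p 0.00237 with an estimated correlation), with Akr1b8 at 0.74 ± 0.04 and Nqo1 at 0.60 ± 0.04. Of 21 genes of the unfolded protein response 11 rose (12 over the list alone; adjusted p 4.46e-08, adjusted p 0.0733 with an estimated correlation), and of 29 genes of ATF4 and the integrated stress response 12 rose (13 and 2 fell over the list alone; adjusted p 5.27e-08, adjusted p 0.172 with an estimated correlation). Of 26 genes of glycolysis and hypoxia 12 rose (12 over the list alone; adjusted p 4.9e-09, adjusted p 0.214 with an estimated correlation). Lists of cholesterol synthesis, AhR targets and p53 targets also passed camera, with adjusted p-values of 0.00388, 0.0409 and 0.0308, and none of the 3 with an estimated correlation (adjusted p 0.244, 0.172 and 0.244). Without indomethacin array 1b the AhR and p53 lists both had an adjusted p of 0.0842, and without SC-560 array 1b they had 0.0556 and 0.0746. The AhR list, with 3 of 5 genes higher, also had 0.0696, 0.0648 and 0.0558 without DMSO array 1b, NS-398 array 1b and NS-398 array 2b. In limma 1768 probe sets were called, 863 higher and 905 lower, of which 153 differed by at least 1.5-fold. The count was 959 without indomethacin array 1b, 923 without indomethacin array 2b and 105 without the label set term.

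**Figure D3:**
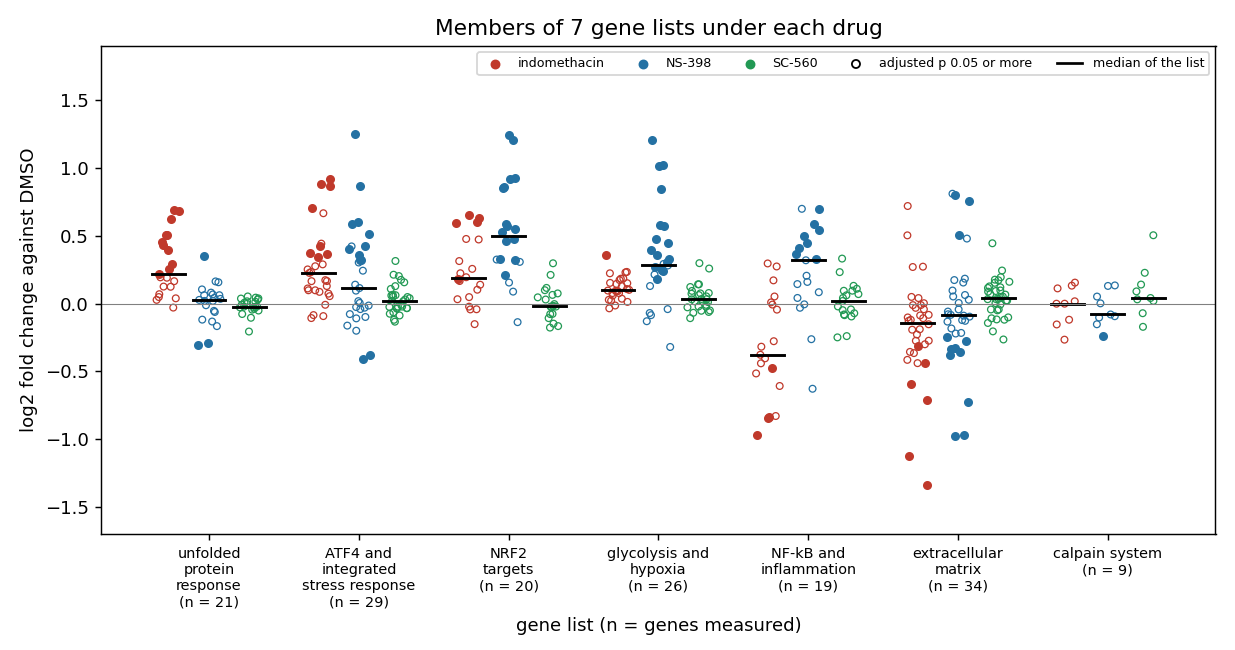
Log2 fold change against DMSO (y axis) of each measured gene in 7 gene lists (x axis) under indomethacin, NS-398 and SC-560; filled points passed an adjusted p of 0.05 in limma and black bars are list medians. Of the 21 unfolded protein response genes 11 rose under indomethacin, of the 20 NRF2 targets 15 rose under NS-398, and no point was called under SC-560.

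Indomethacin and NS-398 differed directly at 954 probe sets in limma, 365 higher under indomethacin and 589 lower. NS-398 enters from both label sets, though its effect differed between them at 958 probe sets, and indomethacin from set b only. Set b alone, which holds both drugs, gave 1630 calls, with 775 of the 954 among them, all in the same direction. The lists and genes that follow come from the fit to both sets. Of 19 genes of NF-kB and inflammation 10 were lower under indomethacin and none higher (median log2 difference -0.65, camera adjusted p 5.14e-10, adjusted p 0.0241 with an estimated correlation), with Tnfaip3, a brake on NF-kB, at -1.43 ± 0.19. Of 21 unfolded protein response genes 11 were higher under indomethacin (adjusted p 6.86e-11, adjusted p 0.0241 with an estimated correlation). Of 20 NRF2 targets 6 were lower under indomethacin and none higher (2.03e-07, adjusted p 0.0241 with an estimated correlation), and so were 7 of 26 genes of glycolysis and hypoxia (2.85e-05, adjusted p 0.384 with an estimated correlation). H19 (-1.57 ± 0.12), Nr4a3 (-1.55 ± 0.26) and Dcn (-1.39 ± 0.13) were lower, and Aldh3a1 (1.12 ± 0.16) and Chac1, a glutathione-degrading enzyme of the integrated stress response (0.96 ± 0.14), were higher under indomethacin, with adjusted p-values of at most 0.00212. The count was 294 without indomethacin array 1b, 261 without indomethacin array 2b and 15 without the label set term.

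Against SC-560, indomethacin differed at 522 probe sets, 205 higher and 317 lower, and NS-398 at 2223, 1122 higher and 1101 lower. Fabp4 was higher under both, by log2 differences of 2.31 ± 0.16 and 1.99 ± 0.12 (limma adjusted p 9.01e-07 and 7.08e-08). Of 21 unfolded protein response genes 12 were higher under indomethacin than under SC-560 (camera adjusted p 4.62e-16, adjusted p 0.0133 with an estimated correlation). Lower under indomethacin than under SC-560 were 5 of 34 extracellular matrix genes (15 over the list alone; 2.56e-07, adjusted p 0.098 with an estimated correlation), 5 of 19 genes of NF-kB and inflammation (8; 0.000114, adjusted p 0.098) and 4 of 12 markers of fibroblasts and smooth muscle (5; 0.00189, adjusted p 0.0998). Of 20 NRF2 targets 17 were higher under NS-398 than under SC-560 (8.8e-20, adjusted p 0.00182 with an estimated correlation). These comparisons were made at 100 µM against 1 µM. For indomethacin the count was 340 with the replicate labels as a block, 147 without indomethacin array 1b, 127 without indomethacin array 2b and 261 without SC-560 array 2b. Without the label set term the counts of indomethacin and NS-398 were 3 and 88, and with a random block for arrays of 1 group and label set, chosen after seeing the data, 273 and 1415; with one for arrays of 1 group and replicate digit they were 685 and 3528.

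The effect of NS-398 depended on the label set for part of the genes. Genes of DNA replication went opposite ways, with a median log2 change of 0.23 over 31 genes in the set without the suffix and -0.16 in set b, and 10 of them differed between the sets. The interaction of this list had a camera adjusted p of 3.33e-12 and an adjusted p of 0.0668 with an estimated correlation, and that of 30 mitotic genes (medians 0.06 and -0.25) 1.36e-09 and an adjusted p of 0.0668 with an estimated correlation. Il33, an alarmin cytokine, changed by 1.04 without the suffix and by -1.33 in set b (limma interaction adjusted p 5.4e-07). Gclm, a subunit of the enzyme that makes glutathione, changed by 1.598 and 0.112, and Aldoa, a glycolytic enzyme, by -0.08 and 0.66 (adjusted p 1.45e-05 for both); these 3 genes were chosen after their values were seen. In limma 958 probe sets differed in this way, 511 with a higher effect in set b and 447 with a lower one, and 195 of them were among the 2366 calls. For SC-560 there were 3, at 1039 with an unadjusted p under 0.05. Its DNA replication list had the same signs (medians 0.07 and -0.05, camera adjusted p 0.00247, adjusted p 0.566 with an estimated correlation), and both drugs were set against the same DMSO arrays. The NS-398 count was 551, 522 and 419 without DMSO arrays 1, 2 and 1b in turn, 554 and 408 without NS-398 arrays 1 and 2, and 330 without the intensity trend.

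Calls of indomethacin and NS-398 against DMSO overlapped. In limma 120 probe sets rose under both, 111 fell under both and 17 were called in opposite directions. Both comparisons use the same DMSO arrays, which produces some overlap without any effect of the drugs. Across probe sets, which are not independent replicates, the log2 changes of the 2 drugs correlated with r = 0.416, where unchanged groups against the same DMSO arrays gave 0.388 in simulation. The covariance was 0.0216, against a simulated 0.00711, and r was 0.240 when each drug was set against different DMSO arrays. For SC-560 the correlation was 0.329 with indomethacin and 0.282 with NS-398 (simulated 0.386 and 0.500), and 0.0455 and 0.0543 with different DMSO arrays.

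Calpains, the calcium-dependent proteases, and cyclooxygenases were followed throughout. Of 9 calpain system genes measured, 1 was called against DMSO under any drug: Capn2, the large subunit of m-calpain, fell under NS-398 (log2 change -0.24 ± 0.05, limma adjusted p 0.00696), from a signal of 3327 ± 140 (SD, n = 4) to 2812 ± 112 (n = 4). In the set without the suffix alone its log2 change was -0.30 with an adjusted p of 0.012, and in set b alone -0.18 with an adjusted p of 0.125. Under indomethacin its log2 change was -0.00045 ± 0.07 and under SC-560 0.04 ± 0.05, and in the combined contrast -0.14 ± 0.04 with an adjusted p of 0.0507. The small subunit Capns1 and the inhibitor Cast had log2 changes of 0.11 ± 0.08 and 0.15 ± 0.13 under indomethacin and -0.10 ± 0.06 and 0.13 ± 0.10 under NS-398, none of them called. For Cast the NS-398 value averages opposite changes, -0.17 without the suffix and 0.43 in set b. The calpain list passed in none of the comparisons with DMSO (camera adjusted p 0.883, 0.428 and 0.33), also not with fry. In the combined contrast it passed with fry but not with camera. Directly against SC-560, Capn2 was lower under NS-398 (-0.28 ± 0.05, adjusted p 0.00258), as were Capn8 (-0.50 ± 0.12, adjusted p 0.0137) and Capns1 (-0.19 ± 0.06, adjusted p 0.0439). The study drew its calpain genes from these arrays. Ptgs2, the gene of cyclooxygenase-2, had log2 changes of -0.36 ± 0.11 under indomethacin, 0.21 ± 0.08 under NS-398 and -0.09 ± 0.08 under SC-560, with adjusted p-values of 0.0729, 0.095 and 0.853. Ptgs1, the gene of cyclooxygenase-1, and the growth factor Ptn stayed below a signal of 100 on all arrays, at highest signals of 51.7 and 74.0, and were not tested.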

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

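Tests written only after their results were seen were those of the hybridisation controls, of genes switched between the label sets, of splits of the arrays and of the effects by set at other pseudocounts. Some of the genes that responded most to NS-398 responded differently in the 2 label sets. Tff2, a trefoil peptide, responded more in set b (the log2 change was higher by 1.77, 0.89 against 2.66), as did Lbp, which binds bacterial lipopolysaccharide (1.58, 0.59 against 2.17), the alcohol dehydrogenase Adh1c (1.56), the protease inhibitor Serpine2 (1.16, 0.25 against 1.40) and Hsd11b1 (0.80). Aldh1a1 (-1.40, 2.74 against 1.34) and the cystine transporter Slc7a11 (-1.09, 1.80 against 0.71) had smaller changes in set b. Falls of Scin (1.19), Them5 (1.18), Postn (1.09), Fam180a (0.74) and Mmp14 (0.42) were smaller in set b, and falls of Tagln (-1.16) and Mat2a (-0.41) larger. Cast, the inhibitor of calpains, changed by -0.17 without the suffix and by 0.43 in set b (difference 0.60, limma interaction adjusted p 0.00237). Across all probe sets 958 differed for NS-398 and 3 for SC-560.

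Several of these sizes depend on the 50 added to each signal, since some DMSO signals were near or under it. Aldh1a1 had mean signals of 46 on DMSO and 192 on NS-398 arrays of set b (4.17-fold), and 672 and 4790 without the suffix (7.13-fold); its difference was -1.05 at a pseudocount of 16 and -1.84 at 200. Tff2, at 6.25 and 14.6 on the DMSO arrays of the sets, had an adjusted p of 0.0909 at 16, and Adh1c one of 0.0512. At 200 the adjusted p was 0.199 for Slc7a11, 0.0633 for Tagln and 0.0543 for Them5. The other 10 genes passed at both pseudocounts. Among them, Scin had mean signals of 85.5 on DMSO and 58.1 on NS-398 arrays of set b, against 642 and 192 without the suffix. Both set b values lie under 100, which left little room for a fall there, and other pseudocounts do not settle this.

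Several causes of this dependence were weighed for the effect of NS-398. DMSO arrays of 1 set out of place would leave few differences when SC-560 is the reference, but there were 869, of which 537 were the same probe sets in the same direction. Signals compressed in 1 set would shrink effects and not turn them, but of 523 probe sets called within each set alone, 89 (17%) had opposite directions. The count of 958 was 551, 522 and 419 without DMSO arrays 1, 2 and 1b in turn, and 554 and 408 without NS-398 arrays 1 and 2. The checks against SC-560 and of opposite directions used the same NS-398 arrays, so NS-398 arrays of 1 set out of place were not tested. Labelling or hybridisation that differed between the sets was not tested for this effect either. A difference in the cells or in the exposure between the sets also stays open. The design names no such difference, so no biological explanation was tested.

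The difference between the label sets themselves covered most probe sets, 10328 of 17515. Brightness left after the authors' scaling would shrink under quantile normalization, but 10129 still differed. Labelling or hybridisation that differed between the sets may contribute: the lowest signal of the cre control without the suffix was 1.38 times the highest in set b, with no overlap. Cells in another state or of another stock may contribute as well, as 6 probe sets lay under 100 on every array of 1 set and at 1000 or more on every array of the other. Xist, the RNA of X inactivation, also differed, with mean DMSO signals of 1.63 and 858.5. These explanations do not exclude each other, and both stay open, as the labels do not say what the suffix marks.

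Log2 changes of indomethacin and NS-398 went together, and shared DMSO arrays produce some of this. Among probe sets called for indomethacin in set b and for NS-398 in the set without the suffix, which share no array, 190 went the same way and 82 opposite ways, a ratio of 2.32, where 55.8 and 55.5 would be expected from independent calls. Shared arrays alone are therefore unlikely to be the whole cause for these calls. Across all probe sets the same changes correlated with r = 0.116 only, and 53.4% had the same sign. For indomethacin in set b and SC-560 in the set without the suffix r was 0.0725, with 52.0%. Indomethacin and NS-398 share the slowing of migration, the blocking of cyclooxygenase-2 and the 100 µM dose in this design. Which of these matters was not tested.

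Other splits of the same arrays were counted, most of them exchanging arrays between the label sets, which differ at most probe sets. For NS-398 against DMSO, 1 of 35 splits gave 2366 calls or more (the real one, highest other 28), and against SC-560 1 of 35 gave 2223 (highest other 6). Splits that keep 2 arrays of each set in each group number 18, too few for a share under 0.05; among them the highest other counts were again 28 and 6. For the combined contrast 1 of 100 drawn splits gave 1768 (highest other 1428, in a draw that kept the same 6 arrays against the same 8, and 69 next). When the groups were drawn again within each label set, 1 of 100 gave 1768 (highest other 104). Arrays of 1 group and set may come from 1 pool, so draws and splits cannot separate drug effects from differences between cultures. For SC-560 against DMSO the real count was 0, so that all 35 splits had to reach it and the test decides nothing. The split by label set gave 1396 there, and 0 for NS-398 against DMSO and for NS-398 against SC-560. In the first, only the NS-398 group still held both sets, so the set term rested on it. That count therefore carries the effect of NS-398 by set. The cause of the counts of 0 was not tested. Chance cannot be excluded for the number of gene lists that passed camera at the preset correlation: 10 of 35 splits gave at least the 8 lists of NS-398 against DMSO (highest other 14), 17 of 35 at least the 3 of SC-560 (10), 8 of 35 at least the 9 of NS-398 against SC-560 (11) and 10 of 100 at least the 9 of the combined contrast (11), or 13 of 100 when drawn within the sets (13).

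Single arrays lay far from the other 3 of their group in 7 of 376 tests. The test, which flags about 1 in 20 by chance, ignored the label sets. Each group held 2 arrays of each set, so that rate does not apply where the sets differ. Akr1b1, an aldo-keto reductase, had a signal of 11480 on DMSO array 1 (others 10030 to 10200) and 8735 on SC-560 array 1 (10350 to 10630). Tff2 had 22.18 on DMSO array 2b (5.24 to 7.27), Tgfb3 1785 on DMSO array 1 (1638 to 1650), Oaz1 16640 on NS-398 array 1b (17980 to 18120), Tnfaip3 1525 on NS-398 array 2b (1915 to 1981) and Nqo1 8277 on SC-560 array 2b (9478 to 9675).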

How the results depend on the processing

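Chosen after seeing the data were the random block of group and set, the correlations across sets and other pseudocounts for the effect by set. Among named genes of the comparisons 5625 values kept direction and call under an alternative, 625 lost the call, 21 gained one and 2 reversed. Without the label set term Tgfbi under indomethacin was 0.59 in place of -0.76, and Acadl in the combined contrast was -0.094 in place of 0.17. Among gene lists 1367 values stayed on their side of the threshold, 54 lost it and 35 gained it. The cause was not tested for the counts below except where fewer arrays or a fold minimum explain them.

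Without the label set term the counts were 2 for indomethacin, 111 for NS-398, 105 for the combined contrast, 3 and 88 for indomethacin and NS-398 against SC-560, and 15 between them. With no filter on signal, indomethacin had 347 against DMSO and 347 against SC-560. Without the intensity trend they were 328 for indomethacin, 320 for it against SC-560, 2 for SC-560, and 330 and 0 for the effects of NS-398 and SC-560 by set. Set b alone gave 1174 for indomethacin, 890 against SC-560, 1630 against NS-398 and 3 for SC-560; the set without the suffix gave 2 for SC-560. Fits to the compared groups alone gave 1248 for indomethacin and 1650 between it and NS-398. A random block of group and digit gave 3708 and 3528 for NS-398 against DMSO and SC-560 and 3 for SC-560; a block of group and set gave 283, 1561, 273, 1415 and 544 for indomethacin, NS-398, each against SC-560, and each other. The replicate block gave 340 for indomethacin against SC-560. At 1.5-fold or more, counts were 211, 322 and 153 for indomethacin, NS-398 and the combined contrast, and 188, 347 and 293 between drugs.

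Lists that passed with an estimated correlation numbered 2, 1, 0 and 1 for indomethacin, NS-398, SC-560 and the combined contrast; fry gave 13, 0 and 14 for the last 3. Correlations with different DMSO arrays were 0.240, 0.0455 and 0.0543 for indomethacin with NS-398, indomethacin with SC-560 and NS-398 with SC-560; across sets, the first 2 were 0.116 and 0.0725.

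Leaving out each array gave 100 to 482 calls for indomethacin, 1659 to 2055 for NS-398, 0 for SC-560, 923 to 1814 for the combined contrast, 127 to 474 and 1516 to 1922 against SC-560 and 261 to 918 between indomethacin and NS-398. Without 1 indomethacin array, the lone array is assumed to vary like the other groups. Lists passing numbered 7 to 12, 7 to 9, 2 to 4 and 7 to 10 for indomethacin, NS-398, SC-560 and the combined contrast. The effect by set ranged from 408 to 758 for NS-398 and 0 to 11 for SC-560, and the correlations from 0.365 to 0.468, 0.263 to 0.403 and 0.235 to 0.347. Signals near background limit genes such as Ptgs1, which were not tested.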

Other observations

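Single genes differed widely between the 2 label sets; the genes named here were chosen after their values were seen, with signals as means of the DMSO arrays and tests of the set term over all 14 arrays. Cdx2, a transcription factor of intestinal epithelium, had a mean signal of 83.4 without the suffix and 3339 in set b. The protease inhibitor A2m had 53.7 and 3945, the matrix protein Tnn 4.40 and 1646, and the secreted phospholipase Pla2g2a 39.3 and 1322. The gap junction gene Gjb2 went the other way, from 4808 to 327, as did the angiotensin receptor Agtr1a (3570 and 312), Slit3 (2332 and 162) and Aldh1a1 (672 and 46.0). Each of these differed in limma, with an adjusted p of at most 1.86e-10 for Aldh1a1. Of 30 mitotic genes 28 were higher in set b and none lower (median log2 difference 0.51, camera adjusted p 2.13e-07, adjusted p 0.443 with an estimated correlation), and of 29 genes of ATF4 and the integrated stress response 25 were higher and 2 lower (median 1.17, adjusted p 8.21e-10, adjusted p 0.252 with an estimated correlation). Of 21 genes of the unfolded protein response, the list that rose under indomethacin, whose arrays are all in set b, 18 were higher in set b and 1 lower (median 0.385, adjusted p 3.43e-05, adjusted p 0.252 with an estimated correlation). The actin list (adjusted p 0.048) and the lists of cholesterol synthesis, of glycolysis and hypoxia and of AhR targets (0.0361 each) also passed, none of them with an estimated correlation. The lists of epithelial markers (adjusted p 0.182) and of growth factors and receptors (0.082) did not pass. In all, 207 probe sets differed by at least 4-fold, 153 higher in set b and 54 lower. Among all 10328 that differed, 5421 were higher in set b and 4907 lower.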
